A study of Sus scrofa with 32 samples.

How the data were processed

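RNA was measured in 12 libraries of pig 2-cell embryos, each made from a pool of 5 embryos, per the labels' protocols. The libraries fall into 4 groups of 3. Embryos came from in vitro fertilisation (IVF) or from parthenogenetic activation (PA), in which the egg is activated without sperm. The sample labels mark the libraries of each kind as antisense against tRNA-Gln-TTG or as control. The series title names small RNAs derived from that tRNA, and the sample labels do not say how the antisense was delivered. The other 20 of the 32 samples in the labels are small RNA libraries, which were not analysed here. The antisense target is itself a small RNA, and the values used here do not measure it, so the strength of the knockdown was not checked.

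Per the labels' protocols, embryos were lysed, ERCC spike-in RNA was added and first-strand cDNA was made by the Smart-Seq2 method. The authors deposited 1 table of FPKM, reads per kilobase of gene model scaled to the library total, for Ensembl gene identifiers with symbol, biotype and position. Per the submitters' processing notes, the names TopHat2 2.0.12 and Sscrofa10.2 apply, with no role stated. The counting tool, the annotation release and the filters are not given in the sources used here, and neither is a use of strand. Reads of overlapping genes or of antisense partners therefore cannot be told apart, and rows with near-identical copies elsewhere, such as YBX1, H2AFX, ribosomal protein genes, 5S_rRNA and SNORA70, are uncertain. Coordinates are those of the table, on Sscrofa10.2, counted from 1 as the table gives them.

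The table holds 19208 rows, of which 35 are ERCC spike-ins and 19173 are genes. Of the gene rows, 634 are at 0 in all libraries. A symbol stands in the table for 11838 gene rows, and the reference name table gave one to a further 2213. Another 23 symbols had been turned into dates by a spreadsheet and were restored by identifier. The remaining 5122 gene rows have no symbol and are counted but not named, with exceptions that are stated where they occur. FPKM values of 1 gene are whole multiples of what 1 read is worth, so reads could be worked out. All 171796 positive values (100.0%) came out whole at a tolerance of 0.001 of a read, with library totals from 9851338 to 14077568 reads. The recovered reads served for depth, for counting intervals and for 1 added alternative.

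FPKM values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, so fold changes are on that scale and understate the change of low genes. The 9326 genes with a mean FPKM of at least 1 over all 12 libraries were fitted with 4 group means, which leaves 8 residual degrees of freedom, and with a variance trend. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The comparisons were antisense against control in IVF embryos, the same in PA embryos, the difference of those effects, and IVF control against PA control. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels do not say that pools came from separate batches or animals, so p-values measure the spread between these libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

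Before the data were examined, 22 gene lists, the alternatives, the design and a rule for named genes were fixed. The rule takes, per comparison, the 8 largest called rises and falls with a symbol and non-overlapping groups, or 5 uncalled genes with the smallest p where fewer exist. It adds up to 4 members of each list with a called member or test, and a fixed panel of 16 genes. Of the panel, CDC20 and ANG fell under the expression filter, and DPPA3 and TRIM28 were not analysed here. Of 1000 distinct list members, 793 were matched in the table and 578 were tested. The matching was narrowed after first values had been seen, because some reference symbols named another gene than the table's own symbol. Lists with at least 5 tested members (21 of 22) were tested with camera at a preset correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were the alternatives. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p is 0.1 for 3 against 3.

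On simulated data with 200 changed genes among 9196 in the PA comparison, the test recovered 37.6% of 2-fold and 87.6% of 4-fold changes over 5 simulations, with 4.43% false calls. For the difference of the effects it recovered 11% and 63.4%, with 7.46% false calls. In 20 simulations of the list test, 20 of 20 moved lists and 0 of 420 unmoved lists were called. The simulated genes were independent of each other. In the data the estimated correlation was 0.214 for ribosomal proteins, 0.111 for nuclear-encoded oxidative phosphorylation and 0.35 for mitochondrially encoded genes. The simulations therefore do not measure false calls for lists whose genes vary together. Libraries of a group differed in their reads by more than counting noise (chi-square per degree of freedom 21.9 to 49.6), so none were merged, which does not show that the pools are independent.

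The labels number the libraries 1 to 3 in each group. Deviations from the group means of PA libraries with the same number correlated at 0.128, 0.191 and 0.167 across genes, and each PA library correlated best with its own number. By this check the numbers may therefore pair the PA libraries, which the labels do not state and 3 libraries per group test only weakly. The same check gave −0.07, 0.21 and 0.12 in IVF libraries, which are not paired by it. The main fit has no block, and blocked fits are among the alternatives.

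Alternatives covered the pseudocount, the filter, 4 scalings, the replicate block, the libraries in the fit, the variance model, the threshold and leaving out each library in turn. Limma voom on the recovered reads, removal of a gene length trend (loess span 0.5), also for the list tests, GO terms and a block within PA embryos were added after seeing the data.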

Results

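The data describe RNA of pig 2-cell embryos, in 12 Smart-Seq2 libraries of 5 pooled embryos each. IVF embryos and PA embryos had the antisense or the control, with 3 libraries per group. Depth was 9851338, 12298523 and 11541708 reads in IVF controls 1 to 3 and 10868468, 10594179 and 11959560 in the IVF antisense libraries. It was 13881786, 14077568 and 12292038 in PA controls and 13124563, 13121866 and 14077502 in PA antisense libraries. Levels are given below as mean FPKM ± SD over the 3 libraries of a group (n = 3), and differences as log2(FPKM + 1) with their standard error (SE) from limma.

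Embryo type set the libraries apart more than the antisense did. The first principal component, with 41.8% of the variance, ran from −32.6 to −17.5 in the 6 IVF libraries and from 5.79 to 34.1 in the 6 PA libraries. PA control 3, at 5.79, lay nearest to the IVF libraries, and the other PA libraries began at 23.9. Mitochondrially encoded genes took 4.14% ± 0.841 of reads in IVF libraries and 2.45% ± 0.328 in PA libraries (SD, n = 6). That difference had an exact two-sided permutation p of 0.002165, the smallest that 6 against 6 can give, and an adjusted p of 0.0108 over 10 measures. Total reads also differed by type, from 9851338 to 12298523 in IVF and from 12292038 to 14077568 in PA libraries (exact permutation p = 0.004329, adjusted p = 0.0144). These tests of 6 against 6 pool control and antisense libraries as if exchangeable and were not in the design fixed beforehand. Between the controls alone, 3 against 3, the exact permutation p was 0.1 for the mitochondrial share and 0.2 for total reads. Both had an adjusted p of 0.692 over 30 tests. ERCC spike-ins held only 154 to 945 reads per library.

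**Figure D1:**
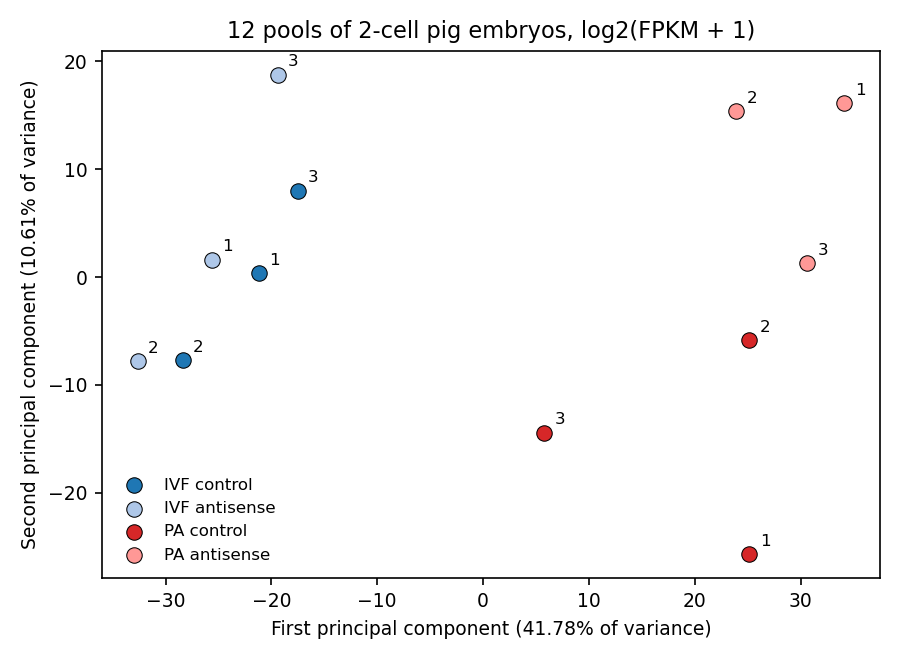
Principal components of log2(FPKM + 1) over the 12 libraries, with the share of variance on each axis, the group as colour and the replicate number beside each point. IVF libraries lie between −32.6 and −17.5 on the first component, PA control 3 lies at 5.79 and the other PA libraries lie from 23.9 to 34.1.

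The first comparison asks which transcripts of fertilised embryos differ when the small RNAs are blocked. In IVF embryos, 2 genes were lower with the antisense and 0 were higher (limma, 9326 genes tested). Neither has a symbol, so both stand outside the rule for named genes and were named after their values were seen. ENSSSCG00000029824, described as mitochondrial transcription factor A, a DNA-packaging protein of mitochondria, went from 4.48 ± 1.35 to 0.135 ± 0.233 FPKM. ENSSSCG00000030046, described as myotubularin-related protein 12, a pseudophosphatase, went from 10.1 ± 2.49 to 3.28 ± 0.819 FPKM.

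ENSSSCG00000029824 lies on chromosome 14 from 100777165 to 100777856 with a gene model of 207 bases. It rested on 11, 13 and 7 reads in the controls against 0, 0 and 1 with the antisense, a ratio of reads of 30.8 (exact 95% interval 5.13 to 1253). Its fitted log2 difference was −2.26 (SE 0.24, limma adjusted p = 0.00125), a size that depends on the pseudocount, and it had 0 reads in all 6 PA libraries. ENSSSCG00000030046 lies on the scaffold GL894605.1 from 1639 to 4574 and had 31, 56 and 34 against 13, 9 and 17 reads. Its log2 difference was −1.37 (SE 0.21, limma adjusted p = 0.0442). A further row with the same description, ENSSSCG00000029555 on scaffold GL893449.1, was not called at −0.49 (SE 0.26, limma adjusted p = 0.666), and the counting may have split reads between these copies. The call of ENSSSCG00000030046 was lost in 22 of 29 alternatives, 10 of which left out 1 library, and that of ENSSSCG00000029824 in 3 of 28.

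Among genes with a symbol, the lowest p-values with the antisense in IVF embryos belonged to values that did not pass. PIBF1, a centrosomal protein, was at 47.9 ± 6.88 in controls and 26.9 ± 0.887 with the antisense, a log2 difference of −0.80 (limma adjusted p = 0.266). The poly(A) polymerase PAPOLG differed by −0.93, the RNase P subunit RPP14 by −0.81, STXBP3 by −0.82 and SUPT20H by −0.48 (limma adjusted p = 0.344 for each). In the other direction, KRR1 and MRPL22, with roles in cytosolic and mitochondrial ribosomes, differed by 0.89 each, PWP1 by 0.77, F2R by 0.72 and CNTROB by 0.55 (limma adjusted p from 0.344 to 0.353). The mitotic kinase CDK1 was at 26.6 ± 10.8 and 15.6 ± 7.09 FPKM, or −0.72 (limma adjusted p = 0.641), and its activator CDC25C was at −0.28 (limma adjusted p = 0.622). CCNB1 at 0.06, CCNE1 at −0.01, WEE2 at 0.07, the deadenylation adaptor BTG4 at 0.06 and the DNA methyltransferase DNMT1 at 0.08 differed by less than 1 SE. The same held for GDF9 at −0.15, SETDB1 at −0.11, POU5F1 at 0.13 and ZP3 at 0.09, and DICER1 was at −0.20 with an SE of 0.20.

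None of the 22 gene lists had a called member in this comparison with limma, adjusted over all genes or over the list alone, and voom called none. At an unadjusted p below 0.05, 5 of 57 genes of the G2/M transition and mitosis were lower and 0 higher, 4 of 45 genes of the G1/S transition were lower and 0 higher, and 2 ribosomal protein genes were higher and 0 lower. Of 24 checkpoint genes 3 were lower and 0 higher, and tRNA and proteasome genes had 2 lower and 0 higher each. Stress genes had 2 higher and 2 lower, and oxidative phosphorylation and histone genes 2 higher and 1 lower each. The other lists had at most 1 in either direction. None of the 21 lists tested passed with camera. The lowest adjusted p was 0.239, for ribosomal proteins (median log2 0.13 over 34 genes), nuclear-encoded oxidative phosphorylation (0.11 over 42) and mitochondrially encoded genes (0.17 over 13). The genes of the G2/M transition and mitosis had a median of −0.08. In limma, 745 genes had an unadjusted p below 0.05 against 466.3 by chance, 502 of them lower. The count of 2 called genes became 0 with a pseudocount of 0.1, with a mean FPKM of at least 5, with only the 6 libraries compared and with limma voom on recovered reads. It was 1 without IVF control 1, IVF antisense 1, any PA control, PA antisense 1 or PA antisense 3.

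PA embryos lack sperm, so the same antisense there asks for effects that need no sperm-borne RNA. In PA embryos, 137 genes fell with the antisense and 0 rose (limma), with a median log2 difference of −1.27 among those called. CENPA, the histone H3 variant of centromeres, fell from 155 ± 27.4 to 18.8 ± 12.9 FPKM. YBX1, an RNA-binding protein that also binds tRNA fragments, fell from 175 ± 22.5 to 36.5 ± 14.8. The cardiolipin synthase CRLS1 fell from 262 ± 23.7 to 49.2 ± 9.15, and NSMCE4A, a subunit of the SMC5/6 complex of DNA repair, from 421 ± 28.0 to 72.0 ± 33.9.

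CENPA had the lowest log2 difference of the named genes, at −3.17 (SE 0.47, limma adjusted p = 0.00335), and lies on chromosome 3 from 119265407 to 119272400. CDCA4, a cell-division-associated gene, followed at −3.09 (SE 0.51, limma adjusted p = 0.00675), with 0, 1 and 10 reads in the antisense libraries against 123, 67 and 83. UBFD1 fell by 2.96 on the log2 scale, the mitochondrial pyrimidine nucleotide carrier SLC25A33 by 2.70, NSMCE4A by 2.66 and the proprotein convertase PCSK5 by 2.65. CRLS1 and the RNA-binding protein RBPMS fell by 2.40 each. The limma adjusted p of these 8 genes lay between 0.0016 and 0.0115. Each was lower in all 3 antisense libraries than in any PA control. RBPMS was the least stable of them, losing its call in 7 of 30 alternatives, among them those without PA control 1 or 3 or PA antisense 1 or 2.

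**Figure D2:**
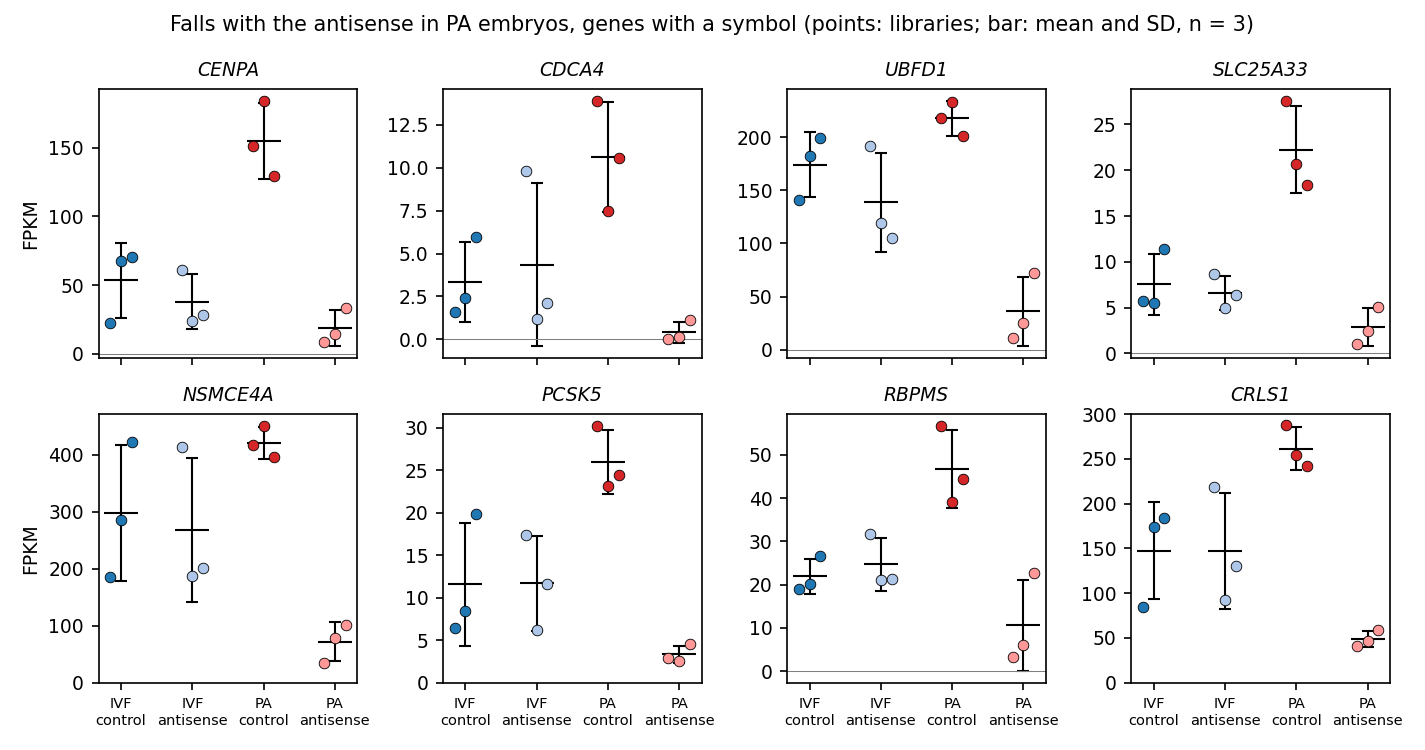
FPKM per library (points) with the group mean and SD (bars, n = 3) for 8 genes with a symbol and large falls in PA embryos, in all 4 groups. In each panel the 3 PA antisense libraries lie under the 3 PA controls, as for CENPA at 18.8 ± 12.9 against 155 ± 27.4, whereas IVF control and IVF antisense libraries overlap.

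The fixed lists held few of the 137 genes. In the list of the G1/S transition and DNA replication, 1 of 45 tested members fell, the clamp loader subunit RFC2, from 161.8 ± 20.04 to 76.0 ± 19.7 FPKM or by 1.11 on the log2 scale (limma adjusted p = 0.00675), and adjusted over the list alone 2 fell. The tumour suppressor RB1, at −1.04, did not pass over all genes (limma adjusted p = 0.0597). In the list of the G2/M transition and mitosis, CENPA was the 1 member of 57 that fell, and CCNB1 at 0.05, CDK1 at 0.53 and CDC25C at 0.06 did not pass. YBX1 was the 1 of 34 members that fell among tRNA processing and small RNA genes, at −2.30 (SE 0.30, limma adjusted p = 0.00175), on chromosome 6 from 156189763 to 156217345, a row whose reads retrocopies could share. In that list DICER1, at −0.49, and AGO2, at −0.39, did not pass. Among stress genes the glutathione reductase GSR fell from 179 ± 6.66 to 104 ± 1.52 (1 of 35), among apoptosis genes the executioner caspase CASP6 from 37.5 ± 0.369 to 17.6 ± 6.66 (1 of 13), and among proteasome genes the ubiquitin-conjugating enzyme UBE2D2 from 7.97 ± 0.498 to 3.45 ± 0.819 (1 of 32). Adjusted over the list alone, 1 stress gene, 2 apoptosis genes and 2 proteasome genes fell. So did 3 each among retrotransposon silencing genes and histones, 1 in the list of the anaphase-promoting complex and its regulators, and 1 cumulus marker. Over all genes these last 4 lists had 0. Voom called 1, 2, 0 and 1 lower in them, and at an unadjusted p below 0.05 limma had 4, 4, 1 and 1 lower. CASP6 lost its call without any 1 of the PA controls or without PA antisense 1 or 3, and UBE2D2 without any 1 of the PA controls or without PA antisense 1 or 2. The other lists, of checkpoint, oocyte and zona, mRNA decay, genome activation, translation, innate sensing, imprinted, mitochondrially encoded, sperm and stroma or blood genes, had 0 called by limma or voom, with at most 3 members lower at an unadjusted p below 0.05.

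Ribosomal protein genes as a list lay higher with the antisense in PA embryos, with a median log2 difference of 0.20, 25 of 34 members positive, 3 higher and 0 lower at an unadjusted p below 0.05 and 0 called singly by limma or voom (limma camera adjusted p = 0.000236). Nuclear-encoded oxidative phosphorylation genes did as well, with a median of 0.25, 33 of 42 positive, 4 higher and 2 lower at an unadjusted p and 0 called (limma camera adjusted p = 0.000869). With an estimated correlation between genes, both had a limma adjusted p = 0.535. The antisense effect in PA embryos fell with gene length, from a median of 0.03 for gene models of up to 914 bases to −0.08 for those of 3619 bases or more, and with that trend removed the lists had limma camera adjusted p-values of 0.00562 and 0.00672. Examples that did not pass singly were RPL14 at 0.72, RPL22 at 0.76 and NDUFA4 at 0.59, while NDUFS6 was at −1.22 in the opposite direction. Both list calls were lost without PA control 1 (limma adjusted p = 0.268 for each) and without PA antisense 2 (0.245 and 0.142). Among single genes the closest to a rise were FAM46C at 0.65, SMIM15 at 0.73, EXT1 at 0.64 and ADCYAP1 at 0.70 (limma adjusted p from 0.0876 to 0.0936).

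Of the fixed panel, POU5F1 was at 115 ± 8.63 in PA controls and 70.7 ± 13.9 with the antisense and did not pass, at −0.71 (limma adjusted p = 0.171). ZP3 was at −0.40, BTG4 at 0.13, SETDB1 at −0.12, CCNE1 at −0.10, GDF9 at 0.11, WEE2 at 0.07 and DNMT1 at 0.07, none of them called. Of the 137 genes, 103 have a symbol, 135 are protein-coding and 108 fell by more than 1 on the log2 scale. All 137 had non-overlapping groups, as had 13.9% of all tested genes against 10% by chance. The count of higher genes was 0 in limma, with 190 higher and 628 lower at an unadjusted p below 0.05, and voom on recovered reads called 2 higher and 182 lower. With the replicate block limma called 2 higher and 112 lower, and with a block within PA embryos 3 and 133. The number of called genes was 36 with no filter, 90 with quantile normalization, with no variance trend or with a gene length trend removed, 68 with only the 6 libraries, and 1 with ERCC scaling, under which the 137 genes had a median log2 difference of −1.33 (quartiles −1.70 and −1.12). It was 54, 78 and 52 without PA control 1, 2 or 3, and 43 and 85 without PA antisense 1 or 2.

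The difference of the antisense effects, IVF minus PA, tests whether the embryo types responded differently. It was called for 5 genes (limma), 4 of them with a fall in PA embryos and a smaller difference in IVF embryos, and 1 without reads in PA embryos. DONSON, a component of the replication fork, went from 52.2 ± 7.08 to 15.1 ± 3.11 FPKM in PA embryos and from 43.8 ± 3.38 to 47.1 ± 4.77 in IVF embryos. The small GTPase ARF6 went from 91.0 ± 22.6 to 28.4 ± 7.74 in PA embryos and from 74.3 ± 6.05 to 92.0 ± 17.4 in IVF embryos.

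The differences of the log2 effects were 1.84 for DONSON (SE 0.24) and 1.86 for the tyrosylprotein sulfotransferase TPST1 (SE 0.25), each with a limma adjusted p = 0.0157. They were 1.95 for ARF6 (SE 0.31) and 1.76 for NAA30, the catalytic subunit of an N-terminal acetyltransferase (SE 0.28), each with a limma adjusted p = 0.034. The last, ENSSSCG00000029824, had a fitted −2.26 (SE 0.33, limma adjusted p = 0.0255) but had 0 reads in all 6 PA libraries, so no effect could be measured there and the value restates the IVF difference. CRLS1 at 2.38 did not pass (limma adjusted p = 0.0657), and neither did EFHC2 at −1.23, MCMDC2 at −1.13, the zona glycoprotein ZP2 at −1.19, the repair nuclease MRE11 at −1.16 and MMADHC at −0.99 (limma adjusted p from 0.125 to 0.151). CDK1 was at −1.25 (limma adjusted p = 0.488). No list passed with camera, the lowest adjusted p being 0.131 for cell cycle inhibition and DNA damage checkpoint genes. The 5 calls became 0 without IVF control 1, IVF control 2, IVF antisense 1, PA control 1 or PA control 2, 1 without PA antisense 1, 2 without PA control 3, 3 without PA antisense 2, 8 without IVF antisense 2 and 59 without PA antisense 3. They became 1 with the replicate block.

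Genes that moved with the antisense in both embryo types were sought next. With limma 0 genes were called in both, against 0.0294 expected for independent lists, and voom also gave 0. At an unadjusted p below 0.05, 13 genes were lower in both against 33.8 expected, and 16 higher in both against 4.95. Across the 9326 genes, which are not independent replicates, the effects correlated at −0.02 (Pearson r). In IVF embryos the 137 genes that fell in PA embryos had a median log2 difference of −0.04, with 58 positive and 79 negative. The difference between the effects was called for 4 of them. The antisense effect in IVF embryos and the PA control minus IVF control difference share the IVF controls. They correlated at 0.188, against 0.5 in simulations of unchanged groups, with a covariance of 0.0276 against 0.0314 simulated (range 0.0292 to 0.0344, 100 simulations), a difference of −0.00382. The simulations set the embryo types equal, while the controls differed in 1325 genes, so the simulated correlation is no benchmark. They also drew genes independently, which makes the simulated range too narrow for genes that vary together. A move toward or away from PA embryos is therefore not decided. The 3 shared controls could be split only unevenly, and no split is given here.

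Fertilised and parthenogenetic controls differed in 1325 genes (limma), 664 of them higher in IVF and 661 higher in PA embryos. Higher in IVF controls were DRAP1, a transcriptional corepressor subunit, at 58.3 ± 17.2 against 11.4 ± 3.40 FPKM, and SKA1, a kinetochore protein, at 261 ± 101 against 80.03 ± 19.44. Higher in PA controls were the syntaxin STX3, at 118 ± 49.5 against 24.9 ± 4.89, and the respiratory complex II subunit SDHC, at 83.4 ± 21.8 against 22.6 ± 5.70. The oocyte growth factor BMP15 was also higher in PA controls, at 1529 ± 350.5 against 622 ± 102.

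Among genes with a symbol, large rises in IVF controls were DRAP1 at 2.25 (SE 0.28, limma adjusted p = 0.00373), RPL11 at 1.71, SKA1 at 1.66, 5S_rRNA at 1.63, CSNK1G2 and COX17 at 1.62 each and the translocon subunit SEC61G at 1.58. The small nucleolar RNA SNORD78 belonged to them on 7 reads in the 3 IVF controls and 0 in the 3 PA controls, at least 2.79-fold higher over the group when 0 reads allow 3. Large falls among genes with a symbol were STX3 at −2.13 (SE 0.34, limma adjusted p = 0.00427), the chaperone subunit PFDN6 at −2.00, H2AFX at −1.87, SDHC at −1.83, SNORA70 at −1.79, CENPA at −1.67, TAGLN2 at −1.64 and UHRF2 at −1.59. The limma adjusted p of these genes lay between 0.00373 and 0.0429. 5S_rRNA rested on 43 reads against 14, a ratio of 3.67 (exact 95% interval 1.97 to 7.26). The call with the smallest adjusted p was ENSSSCG00000029824, with 31 reads against 0, at least 12.3-fold higher over the group (limma adjusted p = 0.000517).

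Cell cycle lists held calls of both signs, and none of them passed with camera. Of 45 G1/S and replication genes, 6 were lower and 1 higher in IVF controls, also when adjusted over the list alone. RFC2 was at −0.94, PRIM2 at −0.77, GINS4 at −0.77 and ORC3 at −0.58, and the cyclin CCNE1 was at −0.53 (53.9 ± 6.57 against 77.8 ± 4.70 FPKM, limma adjusted p = 0.0268). Of 57 G2/M and mitosis genes, 8 were higher and 6 lower, or 9 and 7 adjusted over the list alone. AURKB was higher at 0.58, whereas the checkpoint kinase BUB1B at −1.04, PLK1 at −1.09 and the oocyte CDK1 inhibitor WEE2 at −0.78 were lower. CDK1 at 0.67, CCNB1 at −0.47 and CDC25C at −0.34 did not pass. Of 19 genes in the list of the anaphase-promoting complex and its regulators, 1 was higher, the inhibitor FBXO5 at 1.00. In that list 2 were lower, CDC16 at −0.71 and SKP2 at −0.77. Adjusted over the list alone, 1 was higher and 3 were lower. Of 24 checkpoint genes, 3 were higher, TOPBP1 at 1.11, RAD17 at 0.73 and RAD50 at 0.52, and 1 was lower, H2AFX, with the same counts over the list alone.

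Of 29 oocyte and zona genes, 8 were lower and 1 higher in IVF controls, or 10 and 1 adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.179). BMP15 was at −1.28, the zona glycoprotein ZP3 at −1.17 (30.7 ± 4.97 against 74.3 ± 34.2 FPKM), NLRP9 at −0.84 and TCL1B at −0.81, and GDF9 at −0.55 did not pass. Among 32 mRNA decay genes, 3 were higher, CNOT6L at 0.64 and PAN3 at 0.61 among them, and 2 lower, LSM1 at −1.07 and CNOT3 at −0.80 (3 and 3 over the list alone), with BTG4 at 0.14 not called. Of 29 genome activation genes, NFYB was higher at 0.70 and POU5F1 lower at −0.84 (65.0 ± 16.8 against 115 ± 8.63 FPKM), with the same counts over the list alone. Of 10 imprinted genes, MEST was lower at −1.24, the 1 call over all genes and over the list alone. Of 15 innate sensing genes, TLR7 at −1.09 and MX1 at −0.62 were lower (3 over the list alone).

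Chromatin lists held calls of both signs. Of 39 retrotransposon silencing and heterochromatin genes, 5 were higher in IVF controls, among them the methyltransferases DNMT3A at 1.14 and SETDB1 at 0.79 and the chromodomain protein MPHOSPH8 at 1.04. The other 4 calls were lower, with ASF1B at −0.93 and UHRF2 among them (5 and 6 over the list alone). Of 32 histone and chromatin assembly genes, SUZ12 at 0.88 and NASP at 0.53 were among 3 higher, and NPM3 at −1.23 and HMGN2 at −0.49 among 4 lower (5 and 4 over the list alone). Of 34 tRNA and small RNA genes, 5 were higher, with YBX3 at 1.18, DROSHA at 0.92 and TNRC6B at 0.89 among them, and EPRS was lower at −0.99 (7 and 2 over the list alone). DICER1 at −0.04 and DNMT1 at 0.30 did not pass.

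Mitochondrially encoded genes lay higher in IVF controls as a list, with 5 of 13 called higher, 0 lower and a median of 0.70 (voom 7 and 0; 10 higher over the list alone and at an unadjusted p below 0.05; limma camera adjusted p = 0.000439). With an estimated correlation the limma adjusted p = 0.791, and with fry it was 0.0758. The share of reads on these genes differs by type in the same direction, as given above. COX1 was at 5923 ± 1358 against 2737 ± 468 FPKM (1.10), ND4L at 1.35, ND2 at 0.84 and CYTB at 0.70. Of 42 nuclear-encoded oxidative phosphorylation genes, 9 were lower and 2 higher (10 and 3 over the list alone), the lower ones including SDHC, UQCRC1 at −1.47, NDUFV2 at −1.13 and COX5A (50.6 ± 2.46 against 103 ± 19.6 FPKM), but the list did not pass (limma camera adjusted p = 0.112). Translation factors had 5 higher and 6 lower of 36 (7 and 7 over the list alone), such as EIF4G3 at 0.96, PABPC4 at 0.83, EEF1B2 at −1.21 and EIF3D at −0.99. Ribosomal protein genes had 2 higher, RPL11 and RPS28 at 1.19, and 1 lower, RPS5 at −0.99, of 34, with the same counts over the list alone.

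Stress genes had 7 higher and 3 lower of 35 (9 and 5 over the list alone), such as HSP90B1 at 0.73, GCLC at 0.67, DNAJA1 at 0.45 and the peroxiredoxin PRDX2 at −1.07. Proteasome genes had 2 higher, PSMD11 at 0.99 and PSMD1 at 0.64, and 2 lower, PSMD13 at −0.74 and PSMD8 at −0.44, of 32 (1 and 2 over the list alone). Apoptosis genes (13 tested) and the markers of sperm (6), cumulus and granulosa cells (6) and stroma or blood (4) had 0 called with limma or voom, over all genes or the list alone. At an unadjusted p below 0.05, 1 apoptosis gene and 1 cumulus marker were higher, 1 of each was lower, and 0 of the others were either. No other list passed with camera, the lowest adjusted p being 0.112 for G1/S and replication genes and for nuclear-encoded oxidative phosphorylation. The G1/S list lay lower in IVF controls with fry (limma adjusted p = 0.00828), and with an estimated correlation it did not pass (limma adjusted p = 0.375).

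**Figure D3:**
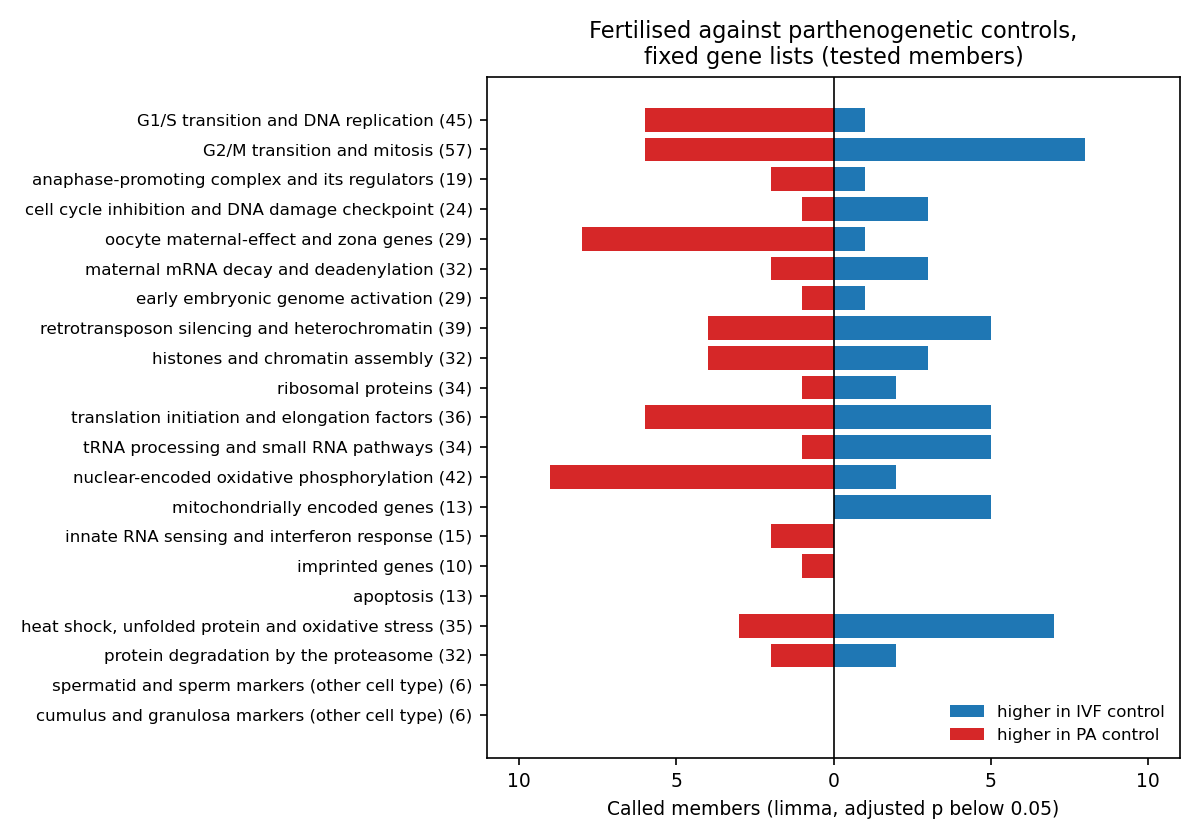
Number of called members (limma, horizontal axis) per fixed gene list with at least 5 tested members in IVF control against PA control, to the right when higher in IVF and to the left when higher in PA, with tested members in parentheses. Mitochondrially encoded genes have 5 calls on the IVF side and 0 on the PA side, and oocyte and zona genes have 1 and 8.

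Non-overlapping groups held for 1296 of the 1325 called genes and for 34.8% of all tested genes, against 10% by chance. Voom on recovered reads called 809 higher and 673 lower. With mitochondrial and the 10 highest genes left out the split was 870 higher and 489 lower, and with ERCC scaling 12 and 2. The count was 675 and 605 without IVF control 1 or 2, and 345 and 501 without PA control 1 or 2.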

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

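The test of genes varying together, those of scaling and of length as the whole source of the fall, the look at which splits kept the PA groups whole and both tests on the Y-linked reads were chosen after the result was seen. The difference of the antisense effects between embryo types passed its test for 5 genes, ARF6 at 1.95, TPST1 at 1.86, DONSON at 1.84, NAA30 at 1.76 and ENSSSCG00000029824 at −2.26 on the log2 scale, of which the last had 0 reads in all 6 PA libraries and only restates its IVF difference. Of 100 splits of the 12 libraries within embryo type, 9 gave at least 5 genes, the real one included, and the highest other gave 98. The other 8 kept the PA groups whole, so the structure of the samples behind their calls is the PA contrast itself and their number does not decide on chance. For the 2 genes lower in IVF embryos, 1 of 10 splits gave as many and the highest other gave 1, and for the 1325 genes between controls 1 of 10 did and the highest other gave 0. Splits of 3 against 3 are too few for a share under 0.05.

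The 137 genes that fell with the antisense in PA embryos came with 0 called higher by limma (190 higher at an unadjusted p below 0.05, 2 by voom, 2 with the replicate block and 3 blocked within PA embryos), and 1 of 10 splits, the real one, gave as many, the highest other giving 0, also among the 3 others that part all 3 pairs, with too few splits for a share under 0.05. Scaling as the whole source of the size of these falls is argued against. Their medians were −1.21 under median-ratio and −1.18 under quantile scaling (upper quartiles −0.98 and −0.95). These scalings moved the median of all genes only from −0.04 to 0.02 and 0.03, too little to make falls of this size. The 137 genes were picked for their falls in the same data, so these medians do not show why 0 were called higher. Their median set against all genes, −1.21 at its nearest to 0, is a measure that such scaling hardly moves and decides nothing. Gene length as the whole source of that size is argued against as well. Removing the length trend, −0.09 at its lowest for these genes, moved their median only from −1.27 to −1.21 (quartiles −1.55 and −0.99). Its removal left 89 genes called (65.0%, or 70.8% when also blocked within PA embryos), fewer than the test asked for. The 48 calls that ended had a median limma adjusted p of 0.04 before (0.00931 for the 89). Their median log2 difference was −1.06 before and −0.998 after, so a part played by length in these 48 cannot be told apart. The 137 genes had a median length of 1372 bases against 1885 for all tested genes. In 5 equal groups of tested genes from shortest to longest, 38, 46, 25, 19 and 9 of them lay. By group medians the trend ran the other way, from 0.03 in the shortest to −0.08 in the longest group. The fitted trend that was removed had a median of −0.08 at the 137 genes. These counts therefore do not decide whether length played a part in the calls. A set of genes that varies between pools of the same group may contribute. In the 6 IVF libraries, 3 of them with the antisense, these genes correlated at a mean of 0.289 after group means were removed. That lay above 100% of 1000 random lists (highest 0.111). Against the PA control mean, their median log2 difference ran from −0.47 to −0.25 in IVF controls and from −0.62 to −0.20 in IVF antisense libraries. It ran from −0.07 to 0.05 in PA controls and from −1.64 to −1.03 in PA antisense libraries. The genes were chosen for being higher in these PA controls than in the PA antisense libraries. Values below the PA control mean in the IVF libraries can thus follow in part from the choice. An effect of the antisense in embryos without sperm stays open beside a set of genes that varies between pools.

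Reads on Y-linked rows numbered 57 in IVF antisense 2, with 31 on DDX3Y and 17 on EIF1AY, against 0 to 5 in the other IVF and 0 to 1 in the PA libraries. Sperm RNA in the pool cannot be told apart from its absence, because 13 sperm or spermatid markers with at most 5 reads in every other library held 5 reads here and up to 13 elsewhere. Cumulus and granulosa cells come from the female egg donor and carry no Y chromosome, so they cannot supply these reads. Markers of cumulus, stroma or blood cells do not decide on other cells in the pool. Here 14 of them, picked in the same way, held 32 reads and up to 11 elsewhere, but those picked so for IVF antisense 3 held 33 reads there. Summed over all members, sperm markers held 950 reads (730 to 1870 in the others), cumulus markers 4272 (4388 to 6422) and stroma or blood markers 558 (493 to 822), levels that could hide a small share. No biological explanation was tested, since the labels do not give the sex of the embryos.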

How the results depend on the processing

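Voom on recovered reads, removal of the length trend, the block within PA embryos and both together were chosen after seeing the data. The 2 genes lower in IVF embryos became 0 with pseudocount 0.1, with mean FPKM of at least 5, with only the 6 libraries and with voom. They became 1 with pseudocount 5, no filter, median-ratio or quantile scaling, the replicate block, no variance trend or the length trend removed, 37 at an unadjusted p below 0.05 and 2-fold, and 1 to 3 when leaving out 1 library. The 137 genes in PA embryos became 36 with no filter (35 of them shared), 90 with quantile scaling, no trend or length removed, 1 with ERCC scaling, 68 with only the 6 libraries, and 43 to 179 when leaving out 1 library. The 5 differences of effects became 2 with pseudocount 0.1 or ERCC scaling, 0 with no filter, 17 with mean FPKM of at least 5, 1 with the replicate block, 37 with quality weights, 273 at an unadjusted p and 2-fold, 22 with voom, and 0 to 59 when leaving out 1 library. The 1325 genes between controls became 716 with no filter, 14 with ERCC scaling, 387 at an unadjusted p and 2-fold, and 345 to 1556 when leaving out 1 library. More rows tested without a filter and fewer libraries change the adjustment by construction, and for the other settings the cause was not tested.

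With the replicate block the PA count was 114 (2 higher, 112 lower), and blocked within PA embryos 136 (3 and 133), or 104 (3 and 101) with the length trend removed as well, while the controls gave 1275. For IVF embryos and the difference of effects the block left 1 gene each, and the block changed no other call of a count or list. Only ERCC scaling, which rests on 154 to 945 reads per library, gave medians of all genes beyond 0.1, at −0.48, −0.12, −0.35 and 0.50 in the 4 comparisons in the order above, against −0.02, −0.04, 0.02 and −0.01 in the main fit. Among called named genes it alone reversed any, CCNE1 (0.0154), HMGN2 (0.0575) and PSMD8 (0.1008) between controls.

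In camera with an estimated correlation, the limma adjusted p was 0.535 for ribosomal proteins and oxidative phosphorylation in PA embryos and 0.791 for mitochondrially encoded genes between controls. With fry it was 0.546, 0.546 and 0.0758, and with the length trend removed 0.00562, 0.00672 and 1.82e-05 (camera). Leaving out 1 library gave 5.31e-07 to 0.268, 5.48e-05 to 0.268 and 0.000116 to 0.00413. The correlation of antisense effects ran from −0.0864 to 0.0433 when leaving out 1 library. That with the control difference was 0.255 at pseudocount 0.1 and 0.115 to 0.347 when leaving out 1 library, the highest without IVF control 3. Named genes kept their side of the threshold in 5130 of their recomputed values, with 420 weaker, 72 stronger and 3 called ones reversed. The 77 called ones between controls lost their call in 1 to 17 settings each. List tests kept their call or lack of one in 1659, with 10 weaker and 7 stronger, among them G1/S genes between controls with fry (limma adjusted p = 0.00828). All 81 library values stayed within their spread. Of 2745 uncalled values of named genes recomputed, 91 changed sign. At this depth, genes with few reads such as SNORD78 cannot show a change under the 3 reads a count of 0 allows.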

Other observations

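All GO term tests and the choice of transposon-derived rows came after the data were seen. Genes of mRNA processing, a GO term, were overrepresented among those higher in IVF than in PA controls, with 29 of 159 against 11.79 by chance (one-sided exact hypergeometric test, adjusted p = 0.00483 over 1066 terms, with 8041 tested genes that have a term as background). CNOT6L and PAN3, both of mRNA deadenylation, belong to the 29. No term passed for genes higher in PA controls (lowest adjusted p = 0.775, exact) or for the genes that fell with the antisense in PA embryos (lowest adjusted p = 1, exact).

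Of 11 tested rows whose description names a transposon or retrovirus, 4 were higher in IVF than in PA controls and 0 lower in limma, as in voom, with 5 and 2 at an unadjusted p below 0.05. A row described as a Gag polyprotein, ENSSSCG00000006978, was at 1.92 on the log2 scale, and TIGD7, PGBD1 and POGK, host genes derived from DNA transposons, were at 1.03, 1.00 and 0.86 (limma adjusted p from 0.00448 to 0.0149). With the antisense, 0 of the 11 were called in either embryo type by limma or voom, with 1 lower at an unadjusted p below 0.05 in IVF and 0 in PA embryos. These rows are gene models and do not measure the repeats of the genome.

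PA control 3 lay between the types, at 5.79 on the first principal component against 23.9 to 34.1 in the other PA libraries and −32.6 to −17.5 in the IVF libraries. RNA of fertilised embryos mixed into this pool is a possible account. Its share came to 0.457 (bootstrap SE 0.0288) from 1484 genes higher in IVF embryos. From 1197 genes higher in PA embryos it came to 0.405 (SE 0.017), a difference of 0.0521 (SE 0.0339). A shift of the pool toward the IVF libraries for another reason could also give similar shares, so their agreement does not decide on mixing. The bootstrap resampled genes, which vary together within a library, so its SEs do not measure the spread between pools. The difference of the shares was 0.289 for PA control 1 and −0.24 for PA control 2. Their references included PA control 3 itself, so they are no clean check of the method. A biological difference between pools of PA embryos, such as in the eggs used, stays open and was not tested. Without PA control 3, limma called 1556 genes between controls in place of 1325 and 52 with the antisense in PA embryos in place of 137.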
